A study of Mus musculus with 24 samples.

How the data were processed

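RNA was sequenced from the retinal pigment epithelium (RPE), the pigmented cell layer that engulfs shed photoreceptor outer segments. Per the labels' protocols, eyes of male mice 6 weeks old were removed and snap-frozen, and the layer was cut out by laser capture microdissection. RNA was extracted with the RNeasy Micro kit, and libraries were made with the KAPA mRNA HyperPrep kit. The mice were wild type or carried altered Per1 and Per2 genes (labelled Per1-/-Per2Brdm1; "knockout" names the libraries with that label), on a mixed C57BL/6/J x 129 SvEvBrd background. Circadian times were CT19, CT22, CT1 and CT10, which the labels place before, during and after the daily peak of outer segment uptake. This gave 8 groups of 3 libraries, 24 in all, each mapped to its group by its labels. Of these, 5 were pooled from 2 eyes, 4 of them knockout and 1 wild type. A library named with a joined number, such as 3and5, is a pool. The labels do not say that every library came from a different animal, so p-values measure the spread between libraries.

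The values analysed are raw read counts per gene as deposited by the authors, whole numbers with no normalization, for 54232 Ensembl gene identifiers. Per the submitters' processing notes, Trimmomatic 0.32, HISAT2 2.1.0, Cufflinks and HTSeq 0.11 were used with genome build GRCm38.p6. Their order and roles, the annotation release and the strand setting of the counting were not given in the sources used here. Counts of genes that overlap another gene on either strand are therefore uncertain. The same holds for genes with near-identical copies, such as ribosomal protein genes, the haemoglobin genes and mitochondrial genes with nuclear copies. No identifier in the table stood for unassigned reads, and 0 columns were left without a sample. Of the identifiers, 54079 were matched to a symbol and 153 were not. A further 98 that shared a symbol with a more abundant gene kept their identifier as a name. Coordinates are from the mouse GENCODE annotation on GRCm38.

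Total counts per library ran from 16245067 to 32066263, with 19030 to 24072 genes detected. The 20 largest genes took 16.4% to 20.9% of the counts, and genes of the mitochondrial genome 2.17% to 5.11%. No pair of libraries of a group was a repeat of one library. Their counts differed by a chi-square per degree of freedom of at least 31.2, and log2(CPM + 1) correlated across genes with r of 0.962 to 0.987.

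Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr over the 8 groups (minimum count 10), which left 20275, and libraries were scaled by TMM. One quasi-likelihood model with robust dispersions held the 8 group means and left 16 residual degrees of freedom, so all groups shared one estimate of the spread. The contrasts were the mean of the 4 knockout minus wild type differences (the genotype average), that difference at each time, any difference over the 4 times within each genotype, and the genotype by time interaction. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. For tests over several times, the value given is the log2 range, the highest minus the lowest fitted log2 value over the times. CPM values were computed with the TMM factors, and errors are SD over 3 libraries or SE of a fitted log2 fold change.

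Gene lists, 30 in all, were fixed in advance. They covered E-box and D-box clock genes, clock genes of the Bmal1 limb, other clock regulators, outer segment uptake, phagosome and lysosome, actin, the visual cycle, melanogenesis and RPE identity. They also covered oxidative phosphorylation, fatty acid oxidation, cholesterol, glycolysis, immediate early genes, heat shock, cold-inducible genes, ER stress, glucocorticoid-induced genes, ribosomal proteins and mitochondrial mRNAs. Marker lists covered rods, cones, inner retina, endothelium, melanocytes, fibroblasts, mural cells, immune cells, blood and muscle. Some lists share members, such as Mlana of the melanogenesis and melanocyte lists. Lists were tested with camera in limma 3.58.1 on voom values, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a contrast. Camera with an estimated correlation was run beside it, as was fry. The 7 list contrasts were the genotype average, the genotype difference at each time, and CT1 against the other times in each genotype. Per1, Per2 and list scores, the mean log2(CPM + 1) of the members per library, were compared with exact two-sided permutation tests that exchanged genotype labels within times (160000 relabellings, 16 tests).

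The tests, lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule named Per1, Per2 and every tested clock list member. For the genotype average it took the 12 largest rises and 12 largest falls among genes past the threshold, with at least 5 CPM on average and the same sign at all 4 times. At each time it took up to 5 rises and 5 falls with that mean. For the time tests it took the 15 smallest p values, for the interaction the 10 smallest, and in each list up to 4 members with the smallest p. Symbols of predicted genes, clones and pseudogenes were not named under the rule.

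Alternatives were RLE scaling, DESeq2 1.42.0, limma voom with library quality weights, no count filter, a minimum mean of 5 CPM, only the groups compared, the replicate number in the library titles as a block, the number of eyes pooled as a covariate, removal of the pooled libraries, a rod score or a choroid score as a covariate, a threshold of 0.10, and removal of each library in turn. For lists they included the estimated correlation, and for scores other pseudocounts. A list that makes up a covariate was left out of the fit with that covariate. The steps were tested on simulated counts for 20275 genes with 200 changed. In the genotype average, 97% of changes of log2 1 were recovered with 14 false calls. For the interaction, 13% of changes of log2 1 and 82% of log2 2 were recovered with 5 false calls. For time in knockout these shares were 45% and 96% with 9 false calls. These values are for edgeR. On separate simulated counts for the genotype average, DESeq2 made 52 false calls and limma voom with quality weights 15. A list raised by log2 0.5 in a simulation over 19647 genes was called by camera with 0 other lists. Genes were drawn independently there, whereas the estimated correlation of the rod list in the genotype average was 0.82. The simulation therefore does not show how often camera falsely calls lists of correlated genes.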

Results

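Gene expression was measured in laser-captured retinal pigment epithelium of wild type mice and of mice labelled Per1-/-Per2Brdm1, at CT19, CT22, CT1 and CT10. Each of the 8 groups held 3 libraries. The series asks whether the clock genes Per1 and Per2 are needed for the daily rhythm of this tissue, which takes up photoreceptor outer segments after subjective dawn. Total counts per library ran from 16245067 to 32066263, and 20275 genes were tested. Values are mean CPM ± SD (n = 3) or log2 fold changes, labelled knockout minus wild type. "Knockout" names the libraries with that label throughout.

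Per1 and Per2, the targeted genes, encode repressors of the circadian clock, and their counts were higher, not lower, in the libraries labelled knockout at CT19, CT22 and CT1. Per1 (ENSMUSG00000020893, GRCm38 chromosome 11, 69095217 to 69109960, plus strand) was at 45.9 ± 5.85 CPM in wild type and 142 ± 35.6 CPM in knockout at CT19. It was at 38.9 ± 12.5 and 126.2 ± 44.8 CPM at CT22, and at 40.3 ± 5.13 and 165 ± 76.3 CPM at CT1. At CT10 it was at 130.6 ± 49.1 CPM in wild type and 95.8 ± 20.5 CPM in knockout. Per2 (ENSMUSG00000055866, chromosome 1, 91415982 to 91459324, minus strand) was at 25.3 ± 4.81 and 106 ± 26.9 CPM at CT19, and at 18.1 ± 8.72 and 106 ± 33.2 CPM at CT22. It was at 15.5 ± 5.90 and 129 ± 21.996 CPM at CT1, and at 137 ± 38.6 and 96.7 ± 5.47 CPM at CT10. Single libraries ran from 24.4 to 186 CPM for Per1 in wild type and 76.9 to 252 CPM in knockout. For Per2 they ran from 10.2 to 160 CPM and 75.4 to 153 CPM. Averaged over times, Per1 rose by log2 1.23 (SE 0.16; adjusted p 9.8e-05) and Per2 by log2 1.79 (SE 0.16; adjusted p 5.0e-07; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Two-sided exact permutation of genotype within times gave p of 0.0006 for Per1 (adjusted 0.0024) and 0.000275 for Per2 (adjusted 0.00173). The Per2Brdm1 allele lacks part of the coding sequence and can still be transcribed. What the altered Per1 gene lacks was not given in the sources used here, and its counts went against its label. Counts summed over all exons do not show a missing part of a gene, so the counts of these 2 genes do not settle the labels, and every direction below rests on them as given.

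**Figure D1:**
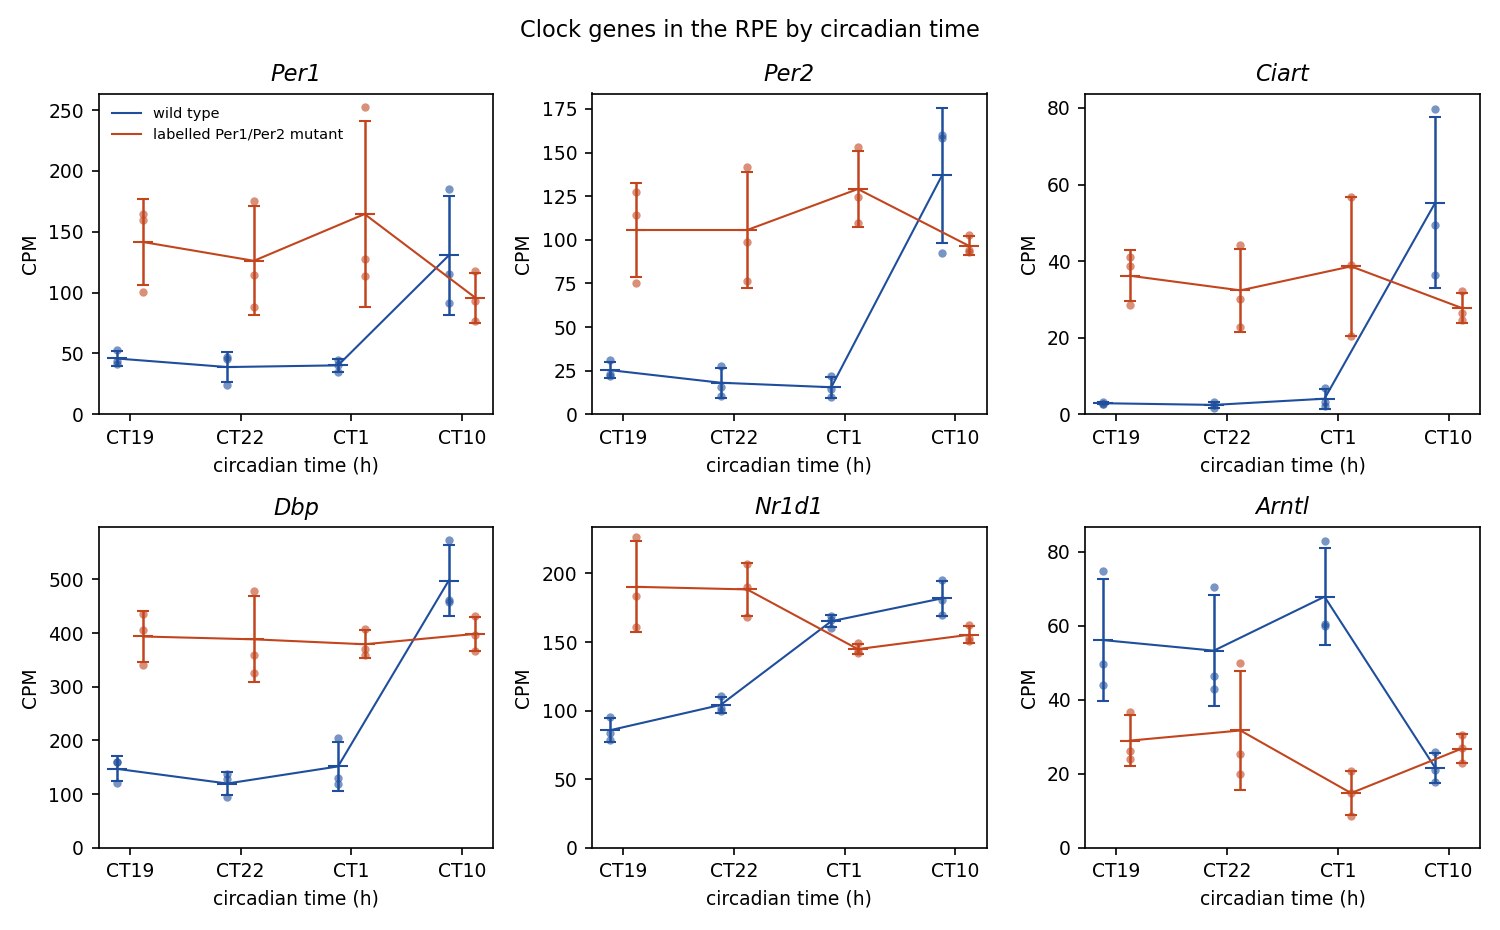
CPM per library (points), with group mean and SD (bars, n = 3, means joined by lines), of 6 clock genes at each circadian time, in wild type (blue) and labelled knockout (orange). Per2 lay at 10.2 CPM in its lowest wild type library and between 75.4 and 153 CPM in all 12 libraries labelled knockout.

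Other clock genes driven through E-boxes or D-boxes rose with Per1 and Per2 in the genotype average, and 3 genes of the Bmal1 limb fell. Ciart, a repressor of the clock activators (ENSMUSG00000038550, chromosome 3, 95878503 to 95882251), rose by log2 2.40 (SE 0.20), and Dbp, an output transcription factor (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203), by log2 1.03 (SE 0.11). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment their adjusted p were 2.3e-07 and 1.5e-06. Ciart was at 2.90 ± 0.31 CPM in wild type and 36.2 ± 6.63 CPM in knockout at CT19, and at 55.3 ± 22.3 and 27.8 ± 4.03 CPM at CT10. The related factors Tef (log2 0.69) and Hlf (log2 0.57) rose too, as did the nuclear receptors Nr1d1 (log2 0.40) and Nr1d2 (log2 0.69), which repress Arntl. So did the repressors Per3 (log2 0.97), Cry1 (log2 0.58), Cry2 (log2 0.72) and Bhlhe41 (log2 0.45), and the deubiquitinase Usp2 (log2 0.79). The activator gene Arntl, which encodes BMAL1, fell by 0.90 on the log2 scale (SE 0.16; edgeR quasi-likelihood Benjamini-Hochberg adjusted p 0.0037). Its partner Npas2 changed by log2 -2.66 (SE 0.43), from at most 6.95 CPM in any wild type library, and the D-box repressor Nfil3 by log2 -0.80 (SE 0.12). Clock, Bhlhe40 and Wee1 did not pass, at log2 -0.18, 0.25 and 0.68. Adjusted over the list alone, 12 of 12 tested E-box and D-box genes rose, against 10 over all genes. In the list of 7 Bmal1-limb genes, 3 fell and 1 rose over all genes, and 4 fell and 2 rose adjusted over the list alone. None of the 10 other clock regulators, such as Csnk1d, passed either way (mean log2 0.02).

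The E-box and D-box list moved as a set. It had a mean of log2 0.80 (camera, Benjamini-Hochberg adjusted p 1.5e-43), and its adjusted p with an estimated correlation was 1.5e-08. The Bmal1-limb list had a mean of log2 -0.46 and a median of -0.17 (camera, Benjamini-Hochberg adjusted p 0.012). Its adjusted p was 0.086 with an estimated correlation, 0.060 with the replicate block and 0.090 at a mean of at least 5 CPM, where its mean was log2 -0.23, so this call did not hold. Per library, the E-box and D-box score was 0.76 higher in knockout (exact permutation p 0.0001125, adjusted 0.00173). The Bmal1-limb score differed by -0.34 (exact permutation p 0.000325, adjusted 0.00173).

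**Figure D2:**
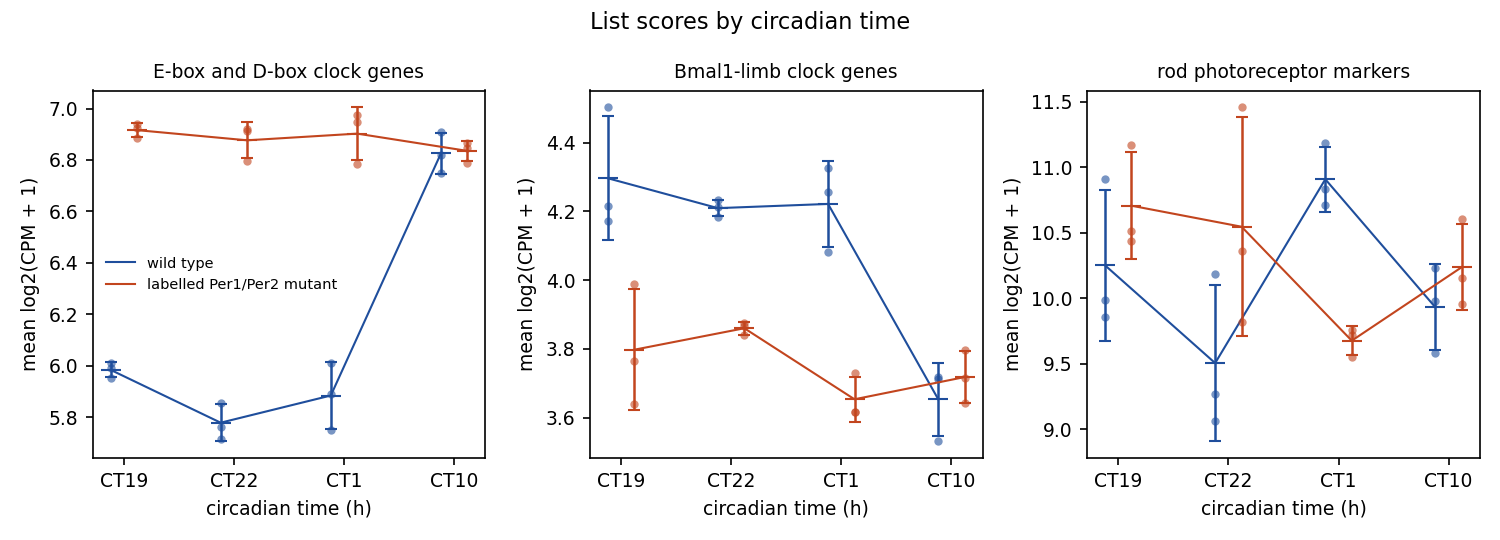
Mean log2(CPM + 1) of the members of the E-box and D-box list, the Bmal1-limb list and the rod list per library (points), with group mean and SD (bars, n = 3, means joined by lines), by circadian time in wild type (blue) and labelled knockout (orange). The E-box and D-box score had a mean of 5.98 in wild type and 6.92 in knockout at CT19, and 6.83 and 6.84 at CT10.

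Outside the clock lists, the largest rise among genes that the naming rule admits was that of Rasl10b, a RAS-like small GTPase (chromosome 11, 83409137 to 83421039), at log2 2.08 (SE 0.20). It was at 13.7 ± 3.75 CPM in wild type and 69.3 ± 31.2 CPM in knockout at CT19. Gzmm, a granzyme-family serine protease gene, rose by log2 1.92 (SE 0.18), and in edgeR's quasi-likelihood test the Benjamini-Hochberg adjusted p of both was at most 4.3e-06. The netrin receptor gene Unc5c rose by log2 1.34, the Hippo-pathway kinase gene Stk3 by 1.21, the phosphodiesterase gene Gdpd2 by 1.05 and Cys1, which encodes a protein of the primary cilium, by 0.97. Coq10b, for a coenzyme Q binding protein, rose by log2 0.90, Plk5 by 0.83 and Ntng1 by 0.76. Among genes that the naming rule admits outside the clock lists, the largest falls were those of the cadherin gene Cdh19 (log2 -1.52, SE 0.30), Ccnjl (log2 -1.43, SE 0.19) and Hcls1, an actin-regulating Src substrate (log2 -1.37, SE 0.16). D2hgdh, for a mitochondrial dehydrogenase, fell by 1.21 on the log2 scale, the myosin chaperone gene Unc45b by 1.18, Syt17 by 1.17, the neuropeptide gene Cck by 1.07 and the sulfotransferase gene Sult1c1 by 1.03. Dbi (log2 -0.69), Fcor (log2 -0.69), Dkk3 (log2 -0.53) and Syne1 (log2 -0.47) fell less. In total 76 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 46 higher and 30 lower, and 1434 had an unadjusted p under 0.05. Rasl10b and Unc45b lie within 20 Mb of Per1, and D2hgdh and Cdh19 within 20 Mb of Per2.

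**Figure D3:**
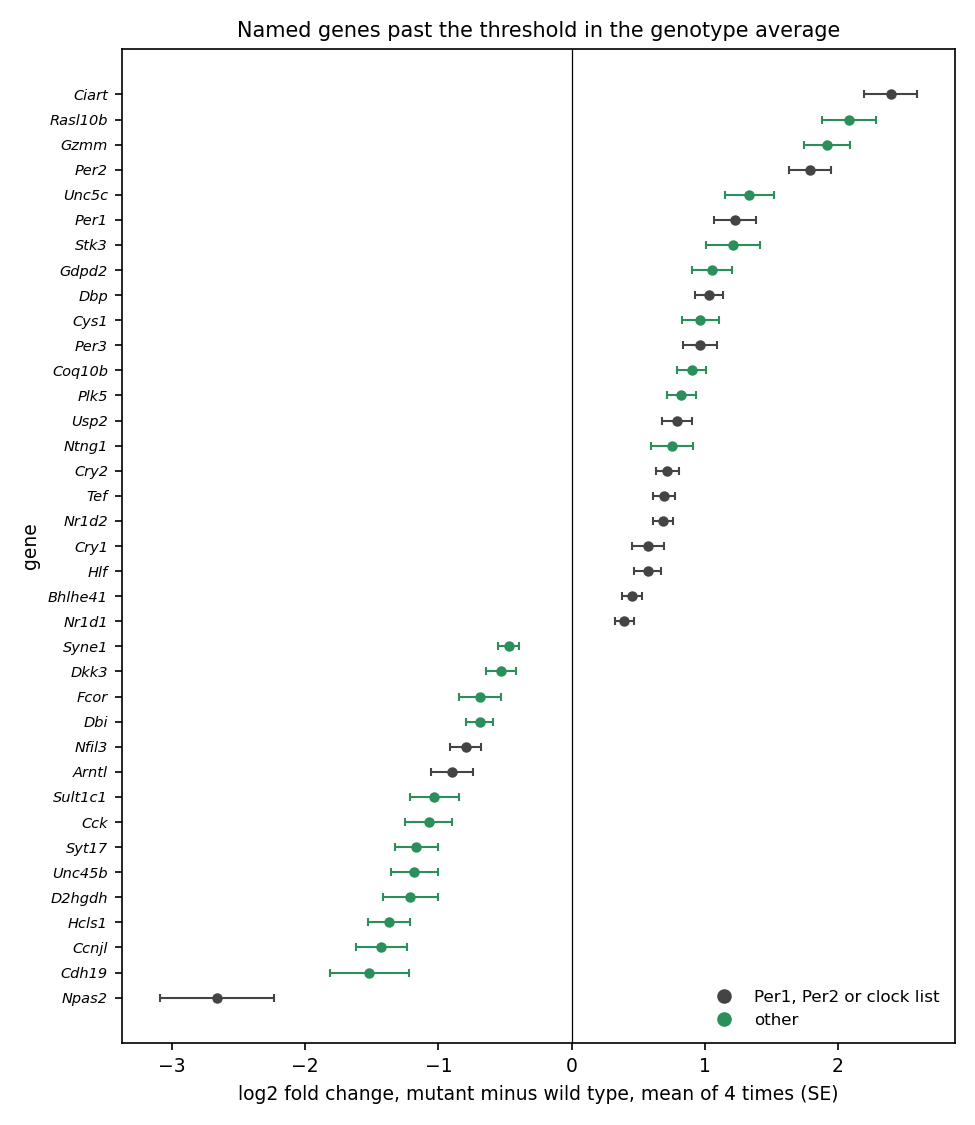
Log2 fold change, labelled knockout minus wild type averaged over 4 times (x axis; bars, SE), of the named genes that passed the test, in grey for Per1, Per2 and clock list members and in green for others. Ciart had the largest rise at 2.40 and Npas2 the largest fall at -2.66.

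The gene lists of uptake and degradation of outer segments did not move with genotype on average. The 26 uptake genes, among them Myo7a and Cd36, had a mean of log2 0.03, and 0 passed over all genes or adjusted over the list alone. The phagosome and lysosome list (38 genes) had a mean of log2 0.04, the actin list (22) -0.0030, the visual cycle list (12) -0.08, melanogenesis (14) -0.05 and RPE identity (26) -0.03, with 0 passing in each. Camera with a preset correlation called 11 of the 30 lists, 2 up and 9 down. With an estimated correlation only the E-box and D-box list held, and fry called 2 lists. The mitochondrial mRNA list had a mean of log2 -0.42 (median -0.27) and the melanocyte list, with the pigment cell gene Mlana, a mean of -0.44 (median -0.30). Their camera Benjamini-Hochberg adjusted p were 1.4e-06 and 0.00015, and with an estimated correlation 0.10 and 0.086. The mitochondrial list held mt-Atp6, mt-Co2 and mt-Co3 (log2 -0.99, -0.89 and -0.85), which were far higher in WT_CT1 replicate 2 than in any other library. The list score differed by -0.33 for mitochondrial mRNAs (exact permutation p 0.00604, adjusted 0.0161) and by -0.40 for melanocytes (exact permutation p 0.00191, adjusted 0.00612). Smaller mean shifts were called with the preset correlation for oxidative phosphorylation (log2 -0.03), fatty acid oxidation (-0.07), cholesterol synthesis (0.19), fibroblasts (-0.22), mural cells (-0.23) and endothelium (-0.14). The adjusted p of these lists with an estimated correlation was at least 0.37. The ribosomal protein list was called down (camera, Benjamini-Hochberg adjusted p 0.037), with a median of log2 -0.04 but a mean of 0.0016, and its adjusted p with an estimated correlation was 0.94. Lists not called were glycolysis (mean log2 0.08), heat shock (-0.01), cold-inducible genes (0.03), ER stress (0.07), glucocorticoid-induced genes (0.01), rods (0.14), cones (0.04), immune cells (0.17) and muscle (0.19). Immediate early genes (mean log2 0.01), inner retina (0.05) and blood (0.01) were not called either, and their test direction was down. Among single members, the glucocorticoid-induced gene Tsc22d3 rose by log2 0.67 and passed.

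At CT19, Ciart rose by log2 3.64 (SE 0.42), Rasl10b by 2.34, Gzmm by 2.26, Per2 by 2.06 and Dbp by 1.42. Syt17, a synaptotagmin gene, fell by 2.04 on the log2 scale, the P-cadherin gene Cdh3 by 1.34, Nfil3 by 1.34, the WNT modulator gene Dkk3 by 1.26 and Dbi, for an acyl-CoA-binding protein, by 1.07. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 14 genes passed (9 higher and 5 lower), and 704 had an unadjusted p under 0.05. The E-box and D-box list had a mean of log2 0.97 (4 of 12 rose, 9 adjusted over the list alone) and the Bmal1-limb list -0.86 (1 fell). Their camera Benjamini-Hochberg adjusted p were 8.9e-31 and 8.2e-05, and with an estimated correlation 1.8e-07 and 0.0075. Camera called 20 lists, 5 up and 15 down, and no others held with an estimated correlation. These included melanogenesis (mean log2 -0.51, 4 genes lower adjusted over the list alone), RPE identity (-0.25), the visual cycle (-0.37), phagosome and lysosome (-0.13) and rods (0.45). Lists of other cell types were called too, with means of log2 -0.82 for blood (4 of 5 genes lower adjusted over the list alone), -0.74 for melanocytes, -0.52 for mural cells, -0.40 for endothelium, 0.52 for cones and 1.76 for muscle. With an estimated correlation the lowest adjusted p of these 11 lists was 0.058, for melanogenesis and melanocytes.

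At CT22, Hkdc1, a hexokinase-domain gene, fell by 2.03 on the log2 scale (SE 0.21; edgeR quasi-likelihood Benjamini-Hochberg adjusted p 1.3e-05). It was at 82.1 ± 12.8 CPM in wild type and 20.1 ± 4.21 CPM in knockout. Ccnjl fell by 1.87, Cdh3 by 1.66, Arhgef37, for a guanine nucleotide exchange factor, by 1.23 and the ephrin receptor gene Ephb3 by 1.16. Ciart rose by log2 3.71, Per2 by 2.54, Gzmm by 2.47, Rasl10b by 2.39 and the sodium-calcium exchanger gene Slc8a3 by 1.86. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 46 genes passed (36 higher and 10 lower), and 2568 had an unadjusted p under 0.05. The E-box and D-box list had a mean of log2 1.15 (camera, Benjamini-Hochberg adjusted p 2.5e-18), with 8 of 12 higher and 10 adjusted over the list alone. Its adjusted p with an estimated correlation was 6.8e-06. The rod list had a mean of log2 1.04 (camera, Benjamini-Hochberg adjusted p 1.0e-11), with 18 of 19 higher adjusted over the list alone, and its adjusted p with an estimated correlation was 0.35. Camera called 10 lists, 3 up and 7 down, and of these only the E-box and D-box list held with an estimated correlation. The lists called down included markers of fibroblasts (mean log2 -0.75), melanocytes (-0.67), mural cells (-0.52) and endothelium (-0.46), opposite to the rod list. Their estimated-correlation adjusted p were 0.35, 0.35, 0.35 and 0.61. With the rod score as a covariate 14 of the genes tested passed at this time, and with the choroid score 17.

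At CT1, Ciart rose by log2 3.23, Per2 by 3.05, Gdpd2 by 2.26, Per3 by 2.14 and Cys1 by 2.04. Hcls1 fell by 2.56 on the log2 scale (SE 0.32; edgeR quasi-likelihood Benjamini-Hochberg adjusted p 0.00016), and Fscn2, a photoreceptor fascin gene, by 2.48. Npas2, at a mean under 5 CPM, changed by log2 -4.04 and passed. Values of log2 -3.12 for mt-Atp6, -2.87 for mt-Co3 and -2.72 for mt-Co2 rested on 1 wild type library. In WT_CT1 replicate 2 these genes were at 72.4, 55.5 and 70.4 CPM. In the other wild type libraries of that time they were at most at 5.06, 3.99 and 6.19 CPM. Without it they were at log2 -0.65, -0.42 and -0.49, with edgeR quasi-likelihood Benjamini-Hochberg adjusted p of 0.51, 0.71 and 0.60. Fscn2 was at log2 -2.20 without that library, with an edgeR quasi-likelihood Benjamini-Hochberg adjusted p of 0.14. Benjamini-Hochberg adjustment of edgeR's quasi-likelihood test left 108 genes (45 higher and 63 lower), and 3960 had an unadjusted p under 0.05. With RLE scaling the split was 69 higher and 58 lower. Leaving out 1 library moved the number passing between 20 and 788. The rod score as a covariate lowered it, as did length and GC slopes as covariates. As a set, the E-box and D-box genes had a mean of log2 1.06 (camera, Benjamini-Hochberg adjusted p 7.5e-14; estimated correlation, adjusted p 4.0e-05), with 6 of 12 higher and 10 adjusted over the list alone. The rod list had a mean of log2 -1.24 (17 of 19 lower adjusted over the list alone), oxidative phosphorylation -0.45, glycolysis -0.67, cones -0.91 and inner retina -0.95. Camera called 14 lists, 5 up and 9 down, and apart from the E-box and D-box list none held with an estimated correlation (adjusted p of the rod list 0.39).

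At CT10 the E-box and D-box list did not differ, with a mean of log2 0.01 and 0 genes passing, also adjusted over the list alone. Its median was log2 0.12 and its test direction was down (camera, Benjamini-Hochberg adjusted p 0.90). Rasl10b rose by log2 2.77 (SE 0.42), Unc45b fell by 2.31 on the log2 scale (SE 0.37), Tspoap1, for a binding partner of a mitochondrial outer membrane protein, by 1.64 and the carbonic anhydrase-related gene Car11 by 1.45. Car11 lies directly beside Dbp on chromosome 7, and its counts are uncertain to that extent. Genes outside the naming rule that passed, given after their values were seen, were Cbln2, Gm15348 and 2610507I01Rik. Benjamini-Hochberg adjustment of edgeR's quasi-likelihood test left 7 genes (3 higher and 4 lower), and 3620 had an unadjusted p under 0.05. With RLE scaling the split was 5 higher and 16 lower. Camera called 14 lists, 12 up and 2 down, and 0 held with an estimated correlation. They included oxidative phosphorylation (mean log2 0.36), phagosome and lysosome (mean log2 0.28, 8 genes higher adjusted over the list alone), inner retina (mean log2 1.13, 4 genes higher adjusted over the list alone) and immune cells (mean log2 0.67), each with an estimated-correlation adjusted p of 0.75. The median fold change of all genes at this time was log2 0.09.

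Over the 4 times in wild type, the clock genes had the widest swings. Ciart spanned log2 4.48, Per2 3.14, Dbp 2.06, Per3 2.00, Per1 1.75, Arntl 1.65, Nfil3 1.61, Tef 1.17, Nr1d1 1.09 and Nr1d2 1.06. Outside the clock lists, Cadm1, an adhesion gene, spanned log2 2.08, Cdh3 1.99, the small GTPase gene Rasl11a 1.83, Hkdc1 1.81, the glutamate receptor gene Gria3 1.55, the water channel gene Aqp1 1.31 and Rnf144b 1.25. Cdh3 was at 422 ± 59.9 CPM at CT22 and 106 ± 26.7 CPM at CT10. Of genes for uptake of outer segments, Mfge8, which encodes a bridging ligand, was the 1 of 26 that passed (log2 range 0.83). No phagosome and lysosome gene passed, also adjusted over the list alone. In the rod list, 2 of 19 genes passed over all genes and 17 adjusted over the list alone. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 192 genes passed, and 3920 had an unadjusted p under 0.05. Of the 192, 93 were highest at CT1, 64 at CT10, 28 at CT19 and 7 at CT22. The number passing depended on single libraries and on CT10. It was 26 without WT_CT1 replicate 2, 29 without WT_CT1 replicate 3and6, 16 without WT_CT10 replicate 1 and 0 without CT10. With CT1 set against the other times, camera called 15 lists, 9 up and 6 down, and 0 held with an estimated correlation. The rod list had a mean of log2 1.02 and the visual cycle list -0.38, with estimated-correlation adjusted p of 0.32 and 0.42. With 4 times and no repeated cycle, these differences do not show a rhythm of 24 hours.

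Over the 4 times in knockout, no gene passed. Ciart spanned log2 0.48, Per2 0.42 and Dbp 0.07, with edgeR quasi-likelihood Benjamini-Hochberg adjusted p of 0.96, 0.95 and 1.00. The smallest p values fell on genes such as the antigen-presentation gene H2-Aa (log2 range 2.28) and the interferon-induced gene Irgm1 (1.39). Their edgeR quasi-likelihood Benjamini-Hochberg adjusted p were 0.12 and 0.20. Beside the 0 genes in edgeR's quasi-likelihood test, 2364 had an unadjusted p under 0.05, DESeq2 called 284 and limma voom with quality weights 0. In simulated counts for the genotype average DESeq2 made 52 false calls, against 14 for edgeR and 15 for limma voom with quality weights. In the immune list 10 of 11 genes passed adjusted over the list alone and 0 over all genes. With CT1 set against the other times, camera called 10 lists, 5 up and 5 down, and 0 held with an estimated correlation. They included oxidative phosphorylation (mean log2 -0.43), rods (-0.82), fibroblasts (0.82) and immune cells (0.70), with estimated-correlation adjusted p of at least 0.51.

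The interaction test asked whether the genotype difference itself changed over the times. Ciart had the largest shift among the genes named, a log2 range of 4.70, from 3.71 at CT22 to -0.99 at CT10. Per2 ranged over log2 3.55, Per3 over 2.87, Arntl over 2.51, Per1 over 2.48, Dbp over 2.02 and Nr1d1 over 1.38. Nr1d1 was higher in knockout by log2 1.15 at CT19 and differed by -0.23 at CT10. Outside the clock lists, Pdzph1, for a PDZ and pleckstrin domain protein, ranged over log2 3.08, Hkdc1 over 2.27, the apoptosis-related gene Aifm3 over 2.14, Rasl11a over 1.96 and the aminopeptidase gene Npepl1 over 1.38. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 937 genes passed, and 4519 had an unadjusted p under 0.05. Relative to wild type, knockout was lowest at CT1 for 641 of them. The lists gave 7 of 12 E-box and D-box genes (8 adjusted over the list alone), 3 of 7 Bmal1-limb genes (3), 14 of 19 rod genes (18), 7 of 16 glycolysis genes (12), 6 of 79 oxidative phosphorylation genes (21), 2 of 26 uptake genes (4) and 1 of 38 phagosome and lysosome genes (0). This count depended on single libraries. It was 20 without WT_CT1 replicate 2 and 1688 without KO_CT22 replicate 1and4. The count also fell with the rod score as a covariate, with length and GC slopes as covariates, and without CT10.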

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

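The tests of linked segments, the rod score on the genotype average, the clock scores of labelled libraries and their range over times, the shared rise of E-box and D-box genes and the GC slope were chosen only after the results were seen.

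The genotype difference changed with circadian time for 937 genes in the interaction test. The log2 range of that difference is given for the 10 genes that the naming rule took by smallest p, not by widest range. Ranges were 4.70 for Ciart, 3.55 for Per2, 3.08 for Pdzph1, 2.87 for Per3, 2.27 for Hkdc1, 2.14 for Aifm3, 2.02 for Dbp, 1.96 for Rasl11a, 1.38 for Nr1d1 and 1.38 for Npepl1. Of 100 splits exchanging genotype labels within times, 1 gave as many genes (the real one, highest other 549), a share under 0.05. Such splits also break up the average genotype difference, so they do not test the interaction alone. The count was 20 without WT_CT1 replicate 2, so its size is not settled.

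A 1st candidate explanation of the many interaction genes outside the clock lists is rod RNA carried into the captured epithelium in unequal amounts. Libraries differed in the rod score, by -1.23 between knockout and wild type at CT1 and by 0.60 at the other times. Within groups, the 266 genes relatively higher in knockout at CT1 had a median correlation with the rod score of -0.27, and the 659 relatively lower ones 0.72, a difference of -0.98 (permutation p 0.0087, 10000 resamples). A 2nd candidate, a trend with transcript length between libraries, gave a difference of 0.88 (permutation p 0.0599), which leaves it open, and the GC slope gave 0.72 (permutation p 0.033). The interaction count fell both with the rod score as a covariate and with length and GC slopes as covariates, which does not tell these candidates apart. A biological effect of the labelled genotype on the times of these genes also stays open.

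The counts of Per1 and Per2 were higher in libraries labelled knockout. A mix-up of single libraries between the genotypes among CT19, CT22 and CT1 is argued against. There the lowest of 9 E-box and D-box clock scores in knockout lay 0.77 above the highest of 9 in wild type. Wild type scores at CT10 (6.75 to 6.91) overlapped the knockout scores at those times (6.78 to 6.98). The gap therefore does not test a mix-up with those CT10 libraries or among knockout libraries. An exchange of all genotype labels would leave the same gap, but would make the libraries with little change over time the wild type ones. The E-box and D-box score had a range over times of 1.05 in libraries labelled wild type and 0.08 in those labelled knockout, and Ciart spanned log2 4.48 and 0.48 (interaction, edgeR quasi-likelihood Benjamini-Hochberg adjusted p 0.00045). These values run as the labels say and argue against an exchange, given that the clock of wild type mice runs. A loss of repression of genes driven through E-boxes or D-boxes may raise transcripts of the altered alleles too, and the other genes of that kind rose (exact permutation p 0.0001125). That rise would follow from any loss of this repression, and whether transcripts lacked exons was not analysed here.

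Genes outside the clock that differed by genotype and did not pass over time in wild type may include strain variants linked to the targeted genes, on the mixed background the labels give. Of 49 such genes, 6 (12.2%) lay within 20 Mb of Per1 or Per2, against 911 of 20181 other genes (4.51%; odds ratio 2.95; Fisher's exact p 0.0227). They were 2610507I01Rik, Unc45b, AA465934 and Rasl10b near Per1 and D2hgdh and Cdh19 near Per2, the clone names being given after their values were seen. Unc45b, AA465934 and Rasl10b lie close together on chromosome 11 (82910550 to 83421039). Fisher's test takes genes as independent, so its p for both segments together may be too small. Neither segment passed alone (Fisher's exact p 0.0771 for Per1 and 0.124 for Per2), the window is 1 choice, and linkage leaves the other 43 genes unexplained. Rod content as the cause is argued against, since 76 of 76 genes of the genotype average stayed past the threshold with the rod score as a covariate. The 49 genes are among them. The rod score differed by 0.14 between genotypes on average (exact permutation p 0.595), so this fit had little to remove. Melanocyte content, with a score difference of -0.40 (exact permutation p 0.00191), was not tested in this way.

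Of 100 splits exchanging genotype labels within times, 1 gave as many genes as the genotype average of 76 (the real one; highest other 3), so chance alone can be excluded. At single times only 10 splits exist, too few to exclude chance. There 1 split, the real one, was as large in each case, with 14 genes at CT19 (highest other 0), 46 at CT22 (highest other 1), 108 at CT1 (highest other 1) and 7 at CT10 (highest other 0). For time in wild type 3 of 100 splits gave at least the 192 genes, a share under 0.05, the limit set for chance. Other splits gave 410 and 310 genes, so a count of this size also arose without the real times. For time in knockout 100 of 100 gave at least the 0 genes (highest other 360). Any split reaches a count of 0, so this share says nothing about chance. Among the other splits, 2 for wild type, 3 for knockout and 3 for the interaction called over 100 genes, as would follow from a structure of the samples or from splits that partly match the real ones, and the cause was not tested.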

How the results depend on the processing

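The alternatives without the 3 libraries at the ends of principal component 4 (WT_CT10 replicate 4, KO_CT1 replicate 1 and WT_CT22 replicate 6), without the 3 farthest from their group means over components 1 to 4 (KO_CT1 replicate 5, KO_CT22 replicate 2 and KO_CT19 replicate 2), without CT10, and with length and GC slopes as covariates were chosen only after the data were seen.

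No score past the threshold changed sign in any setting run, nor did any named gene past it in the genotype average or at single times. The tests over several times give a range, which has no sign to change. Of the 37 named genes past the threshold in the genotype average, 20 stayed past it in every setting, among them Per1, Per2, Ciart, Dbp, Npas2, Rasl10b and Gzmm. Of those named at single times, 1 of 10 did so at CT19, 2 of 10 at CT22, 2 of 10 at CT1 and 0 of 4 at CT10, and 0 of 18 over time in wild type and 0 of 17 in the interaction. Without CT10 no gene passed over time in wild type or in the interaction, which alone fixed these last counts of 0. Over time in wild type Ciart, Per2, Per3 and Dbp each stayed past the threshold in 39 of 40 settings, but Arntl in 14. In the interaction Per2 stayed past it in 38 of 39 settings, but Nr1d2 in 22. Scores kept their side of the p threshold in 27 of 27 settings except melanocytes and mitochondrial mRNAs, each 26, with highest adjusted exact permutation p of 0.0517 and 0.0573. Of the scores that did not pass, the difference changed sign for blood (-0.145 to 0.0728), cones (-0.0852 to 0.106), inner retina (-0.113 to 0.0666), muscle (-0.356 to 0.197) and ribosomal proteins (-0.0957 to 0.0632). The counts reported were 76 for the genotype average, 14 at CT19, 46 at CT22, 108 at CT1, 7 at CT10, 192 for time in wild type, 0 for time in knockout and 937 for the interaction. Counts moved by over 1.5 times follow by setting (those with an exponent are rounded to 2 digits), and the cause was not tested, except that removing libraries or times leaves fewer samples and a threshold of 0.10 admits more genes. DESeq2 called 176 for the genotype average, 37 for CT19, 313 for CT22, 1107 for CT1, 769 for CT10, 1441 for time in wild type, 284 for time in knockout and 2501 for the interaction. Its false calls in simulated counts for the genotype average were 52, against 14 for edgeR. No count filter gave 378 for the genotype average, 1.2e+02 for CT19, 808 for CT22, 1556 for CT1, 999 for CT10, 2159 for time in wild type, 1253 for time in knockout and 2686 for the interaction. Limma voom with quality weights gave 31 for CT19, 14 for CT22, 364 for CT1, 1471 for CT10, 2683 for time in wild type and 2486 for the interaction. Only the groups compared gave 4 for CT19, 2 for CT22, 693 for CT1, 918 for CT10 and 881 for time in wild type. The rod score as a covariate gave 1.2e+02 for the genotype average, 14 for CT22, 13 for CT1, 84 for CT10 and 28 for the interaction. The choroid score gave 17 for CT22, 22 for CT10, 1050 for time in wild type and 140 for the interaction. Length and GC slopes gave 17 for CT22, 9 for CT1, 2 for CT10, 21 for time in wild type and 9 for the interaction. Without the pooled libraries counts were 3 for CT19, 12 for CT22, 8 for CT1, 74 for CT10, 25 for time in wild type, 2 for time in knockout and 298 for the interaction. With eyes pooled as a covariate they were 9 for CT19 and 11 for CT10. Without the 3 libraries at the ends of component 4 they were 8 for CT19, 15 for CT22, 28 for CT1, 1 for CT10, 24 for time in wild type and 14 for the interaction. Without the 3 farthest libraries they were 17 for CT22, 237 for CT1, 617 for CT10, 1212 for time in wild type and 553 for the interaction. Without CT10 they were 0 for time in wild type and 0 for the interaction. A threshold of 0.10 gave 1.2e+02 for CT22, 966 for CT1, 144 for CT10, 845 for time in wild type and 2219 for the interaction. A mean of at least 5 CPM gave 202 for CT1 and 31 for CT10, and RLE 21 for CT10.

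The replicate block used the numbers in the library titles, which the labels do not say pair animals. It gave 36 for the genotype average, 2 for CT19, 4 for CT22, 3 for CT1, 15 for time in wild type and 3 for the interaction. Deviations from group means correlated with a median r of 0.011 over 30 pairs with the same number (-0.213 to 0.422, 7 over 0.1) and -0.015 over 222 pairs with different numbers (-0.461 to 0.406, 57 over 0.1), across genes, which are not independent replicates. This showed no pairing by number, but 30 pairs with this spread cannot exclude a shared batch.

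Leaving out each library in turn moved the genotype average between 65 and 86. CT19 ran from 3 to 17, with 9 without WT_CT19 replicate 1, 6 without replicate 2, 5 without replicate 4, 7 without KO_CT19 replicate 2 and 3 without replicate 3and5. CT22 ran from 12 to 316, with 20 without WT_CT22 replicate 1, 15 without replicate 6, 80 without KO_CT22 replicate 1and4, 12 without replicate 2 and 316 without replicate 3. CT1 ran from 20 to 788, with 60 without WT_CT19 replicate 4, 20 without WT_CT1 replicate 2, 32 without replicate 3and6, 63 without WT_CT10 replicate 2, 788 without KO_CT22 replicate 2, 213 without replicate 3, 36 without KO_CT1 replicate 1, 60 without replicate 4and6, 33 without replicate 5, 70 without KO_CT10 replicate 2 and 62 without replicate 3and5. CT10 ran from 1 to 33, with 4 without WT_CT19 replicate 1, 12 without WT_CT22 replicate 1, 11 without replicate 3, 14 without WT_CT1 replicate 3and6, 17 without replicate 5, and 2, 3 and 2 without WT_CT10 replicates 1, 2 and 4. It was 33 without KO_CT19 replicate 2, 4 without replicate 3and5, 32 without KO_CT22 replicate 1and4, 30 without replicate 2, and 1, 4 and 1 without KO_CT10 replicates 2, 3and5 and 4. Time in wild type ran from 16 to 686, with 110 without WT_CT19 replicate 2, 98 without replicate 4, 106 without WT_CT22 replicate 1, 88 without replicate 6, 26 without WT_CT1 replicate 2, 29 without replicate 3and6, and 16, 43 and 31 without WT_CT10 replicates 1, 2 and 4. It was 686 without KO_CT22 replicate 2, 1.2e+02 without KO_CT1 replicate 1, 103 without replicate 4and6, and 1.1e+02, 103 and 1.1e+02 without KO_CT10 replicates 2, 3and5 and 4. Time in knockout ran from 0 to 3, with 1 each without WT_CT19 replicate 1, WT_CT22 replicates 3 and 6, WT_CT1 replicate 5, KO_CT19 replicate 4 and KO_CT1 replicate 4and6, and 3 without KO_CT10 replicate 2. The interaction ran from 20 to 1688, with 404 without WT_CT19 replicate 4, 162 without WT_CT22 replicate 1, 395 without replicate 6, 20 without WT_CT1 replicate 2, 30 without replicate 3and6, and 46, 508 and 172 without WT_CT10 replicates 1, 2 and 4. It was 610 without KO_CT19 replicate 4, 1688 without KO_CT22 replicate 1and4, 1480 without replicate 3, 82, 94 and 35 without KO_CT1 replicates 1, 4and6 and 5, 102 without KO_CT10 replicate 2 and 37 without replicate 4.

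Over the settings run, the lists called by camera numbered 5 to 13 for the genotype average, 15 to 24 at CT19, 6 to 19 at CT22, 8 to 19 at CT1 and 9 to 14 at CT10, leaving aside the estimated correlation. In 24 cases a list's test direction reversed, with these mean log2 values. For oxidative phosphorylation in the genotype average they were 0.034 with the replicate block, 0.020 with eyes pooled, 0.018 without the pooled libraries and 0.013 without KO_CT22 replicate 1and4 (lowest without 1 library -0.094), and for ribosomal proteins 0.062 with the block and 0.050 without the pooled libraries. Phagosome and lysosome at CT19 had 0.025 without the pooled libraries and 0.014 without KO_CT19 replicate 3and5 (lowest without 1 library -0.26). With the rod score as a covariate, glycolysis had -0.041 at CT19 and -0.059 at CT22, the visual cycle 0.074, RPE identity 0.16 and endothelium 0.25 at CT22, and ribosomal proteins 0.046 and fibroblasts -0.39 at CT1. For CT1 against the other times in wild type, that covariate gave RPE identity 0.22, oxidative phosphorylation -0.037, glycolysis 0.023 and ribosomal proteins -0.15, and the block gave RPE identity 0.061 and cholesterol 0.061. In knockout it gave ribosomal proteins -0.024 and endothelium -0.10, and the choroid score gave ribosomal proteins -0.0032. The cause was not tested. Only the groups compared gives no separate value for the genotype average and the interaction, which use all groups.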

Other observations

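The tests of scores over time given here were chosen only after the results were seen.

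In the libraries labelled knockout the immune marker score had means of 2.95 ± 0.19 at CT19, 3.12 ± 0.39 at CT22, 3.91 ± 0.34 at CT1 and 4.17 ± 0.26 at CT10 (SD, n = 3). In wild type the means were 3.07, 3.28, 3.50 and 3.59. The antigen-presentation gene Cd74 was at 29.0, 39.5, 69.9 and 133.6 CPM in knockout and at 34.9, 54.4, 67.0 and 60.2 CPM in wild type, in the same order of times. H2-Aa, of the same pathway, was at 11.5, 16.3, 28.0 and 55.5 CPM in knockout and at 13.9, 19.1, 27.1 and 23.3 CPM in wild type. The exact permutation p of the score over times was 0.00539 in knockout, which failed adjustment over 32 tests (adjusted p 0.0575), and 0.380 in wild type. Of other scores in knockout, inner retina had an exact permutation p of 0.0187 (adjusted 0.0997), fibroblasts 0.0467 (adjusted 0.177), muscle 0.0688 and mural cells 0.0713 (each adjusted 0.207). Of the 11 genes of the immune list, the interaction test (edgeR quasi-likelihood with Benjamini-Hochberg adjustment) called 0 over all genes and 0 adjusted over the list alone, so a difference between the genotypes over time was not found in these genes. The E-box and D-box score over times had an exact permutation p of 0.00169 in wild type (adjusted 0.0540) and 0.501 in knockout, and the rod score 0.0385 (adjusted 0.176) and 0.126.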
